A study of Arabidopsis thaliana with 12 samples.

How the data were processed

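Transcript levels were measured in whole Arabidopsis thaliana seedlings grown for 3 days in the dark, on 12 Affymetrix arrays. The 12 arrays fall into 6 groups of 2 replicates: the wild type Col-0, the ethylene-overproducing mutant eto1-4, and eto1-4 grown with 10 µM of 9393, 9370, 7303 or AVG. AVG is aminoethoxyvinylglycine, an inhibitor of enzymes that use pyridoxal phosphate, among them ACC synthase of the ethylene pathway. The 3 compounds with number codes are described here by their codes alone.

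The deposited table gives 1 signal intensity per probe set and array on a linear scale. Per the submitters' processing notes the authors made these intensities with MAS5, for which no version is stated, and the settings are not given in the sources used here. The mean of the deposited signals after trimming 2% lay between 500.039 and 500.045 on all 12 arrays, so each array had been scaled to the same trimmed mean. The median signal ranged from 156 to 190.0 between arrays. No detection calls were used, and no pair of arrays held identical values. The number of arrays, 2 per group, limits the precision.

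The table holds 22810 probe sets, of which 64 are array controls and were left out of the tests. The deposited intensities were taken to log2 after adding an offset of 22.4, the 20th percentile of all signals, and fold changes are therefore on the log2(signal + offset) scale, which understates the change of dim genes. The size of a change depends on this offset where a group mean lies below it, as it does in at least 1 comparison for CYP718, XTH26, AT2G22930, LBD29, AT2G17600, AT2G30540, AT1G72290, AT1G53080, AT5G57670, AT2G16005, AT2G43140, THI2.2 and AT5G04120. A probe set was tested if its signal lay above the array's 40th percentile on at least 2 arrays, which left 14830. Genes were named through the platform annotation, updated by gene identifier to the locus tags and symbols of assembly TAIR10.1. Of all probe sets, 13436 named 1 gene, 503 named several, 77 named a gene that matched no locus tag, and 8730 were not listed with a gene and are unnamed here. Among the tested probe sets 7995, or 53.9%, named 1 gene. ETO1 itself was not among the named genes and is not analysed here, nor are most of the well-known ethylene genes.

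All 12 arrays entered a single linear model with 6 group means in limma 3.58.1 under R 4.3.3, with an intensity trend in the moderated variance, 6 residual and 4.07 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 16 comparisons, and a probe set was called at an adjusted p under 0.05. Every adjusted p given for a gene comes from this limma fit unless another is named. The labels speak of independent sets of arrays without tying arrays to separate cultures, so p-values measure only the spread between these samples, which may be technical. The script was tested on simulated data for eto1-4 against Col-0, with 200 of 14830 genes changed in each of 5 simulations. It recovered 34.6% of changes of 1 on the log2 scale, 94.8% of changes of 2 and 98.9% of changes of 3, and 5.99% of its calls were false. The simulated noise was independent, with no deviation shared between arrays and no array that stands apart. These rates may therefore not hold for the data.

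For the probe sets called in eto1-4, the share of the shift left under a treatment was the distance of the treated mean from Col-0 divided by the distance of untreated eto1-4 from Col-0. It was set beside 20 simulations with no treatment effect, since picking probe sets by their change in eto1-4 moves this share below 100 on its own. These simulations took the observed eto1-4 changes as true and called 1450 to 1681 probe sets, against 326 in the data. After the data were seen, 20 more were therefore run with the eto1-4 changes shrunk to 70%, which called 241 to 406. Both sets use independent noise and hold no array that stands apart. Correlations between treatments were set beside simulated unchanged groups that share the untreated eto1-4 arrays.

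The design, the gene lists, the rule for named genes and the other settings to be run were fixed before the data were examined. Of 499 genes on 32 lists, 60 were measured and named, 5 lists had no measured member and 18 had 1 or 2. The 9 lists with at least 3 members were tested with camera at a preset correlation of 0.01, adjusted over 45 tests, with 1 probe set per gene, the brightest. They were ethylene perception and signalling, auxin-responsive genes, gibberellin metabolism and response, xenobiotic detoxification, expansins, xyloglucan endotransglucosylases, seed storage and late embryogenesis, cell cycle, and reference genes. Camera with an estimated correlation and fry were the alternatives.

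The rule for named genes took, for each of the 5 main comparisons, the 10 genes that rose most and the 10 that fell most among called probe sets naming 1 gene and changed the same way in both pairs of equal replicate number. It added called members of the ethylene lists (or, where fewer than 3 were called, the ethylene-induced members with the lowest p) and up to 4 called members of each other list described. For the other comparisons it took the 5 that rose most and the 5 that fell most. It put ETO1 first, which could not be followed here.

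The other settings were no offset, double the offset, no filter, a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, the replicate number as a block, a fit of only the groups compared, a minimum log2 change of 1, and leaving out each array in turn. After the data were seen, the control probe sets for poly-A spike RNA, which is added to a sample before labelling, showed a labelling batch. The spike signal (dap 3' probe set) was 0.931 to 7.99 on 4 arrays, namely replicate 1 of Col-0, eto1-4, 9393 and 9370, and 149 to 414 on the other 8. A fit with this batch as a block and a fit of the 8 spiked arrays were then added, as were a test of gene families sharing a symbol and gene lists with each array left out.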

Results

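The study asked how 3 compounds found as antagonists of the ethylene response, and the known inhibitor AVG, act on transcripts of the ethylene-overproducing mutant eto1-4. ETO1 encodes a protein that targets a class of ACC synthases for degradation. Each of 12 arrays held RNA of whole seedlings of Arabidopsis thaliana, 3 days old and grown in the dark. There were 2 arrays each for Col-0, untreated eto1-4, and eto1-4 with 10 µM 9393, 9370, 7303 or AVG. The deposited MAS5 signals had the same trimmed mean on every array, and 14830 probe sets were bright enough to be tested.

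The control probe sets divided the arrays into 2 sets, called labelling batches here, though no label names a batch. Poly-A spike RNA was present on 8 arrays and absent from replicate 1 of Col-0, eto1-4, 9393 and 9370, so these 4 groups straddle both labelling batches while both replicates of 7303 and AVG carry the spike. The 3'/5' signal ratio of the GAPDH control lay between 1.60 and 2.02 on the 4 unspiked arrays and between 1.18 and 1.53 on the 8 spiked arrays. The control probe set bioB 3' read 348 to 442 on the unspiked and 210 to 303 on the spiked arrays. The probe set for 25S ribosomal RNA read 208 and 266 on the Col-0 arrays and 494 to 12724 on the 10 arrays of eto1-4 seedlings, treated or not. The means differed by 4.14 on the log2 scale. Every comparison with Col-0 therefore also sets a low against a higher 25S signal.

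**Figure D1:**
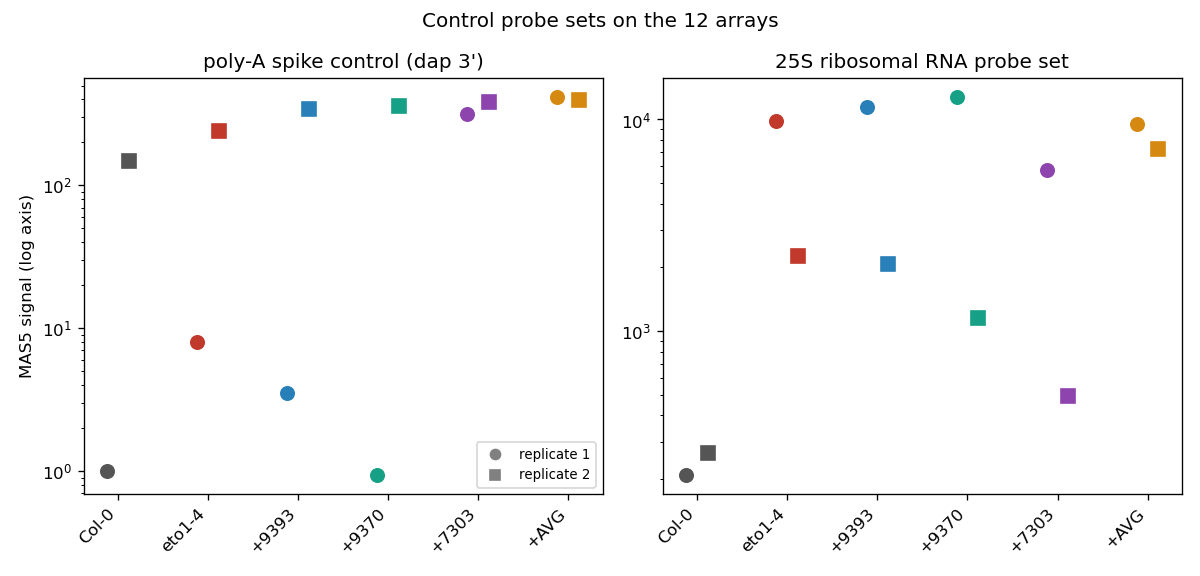
MAS5 signal (log axis) of the poly-A spike control dap 3' and of the 25S ribosomal RNA probe set on each of the 12 arrays, by group, with circles for replicate 1 and squares for replicate 2. The spike read at most 7.99 on 4 arrays and at least 149 on the other 8, and the 25S signal was at most 266 in Col-0 and at least 494 elsewhere.

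Between eto1-4 and Col-0 seedlings, the gene that rose most was AT2G39980, by 4.15 ± 0.47 (SE) on the log2 scale (adjusted p = 0.00647), from a signal of 275 ± 103 (SD, n = 2) in Col-0 to 5105 ± 271 in eto1-4. Here and below, genes that rose or fell most are taken only from called probe sets that name 1 gene. The peroxidase family gene AT5G19890 rose by 3.53 ± 0.54, the cytochrome P450 gene CYP718 by 3.32 ± 0.51, and XTH26, a xyloglucan endotransglucosylase, by 3.00 ± 0.51. The gene that fell most was AT4G11190, of the dirigent family, at -3.95 ± 0.21 (adjusted p = 5.77e-05), with a signal of 3227 ± 251 in Col-0 and 187 ± 7.40 in eto1-4. AT1G72140 followed at -3.59 ± 0.79 (adjusted p = 0.0488). PME61, a pectin methylesterase, stood at -3.29 ± 0.46 and the sugar transporter gene SWEET17 at -2.92 ± 0.61.

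The other genes that rose most were AT5G57760 at 3.47, AT5G50335 at 3.34, AT3G28310 at 3.28, AT5G02540 at 3.18, the dehydrin family gene AT4G38410 at 3.12 and the glutaredoxin family gene AT4G15700 at 3.11. The other genes that fell most were AT2G25150 at -3.05, AT4G25780 at -2.93, AT1G10640 at -2.85, the dirigent family gene AT4G11210 at -2.82, AT2G22930 at -2.54 and AT5G35940 at -2.45. RTE1, which acts on the ethylene receptor ETR1, rose by 2.11 ± 0.30 (adjusted p = 0.0127). EIN3, a transcription factor of the ethylene pathway, differed by 0.26 and ETP2 by -0.08, and neither passed the test. In all, 1 of the 3 measured genes of ethylene perception and signalling rose. As a list they did not pass camera (adjusted p = 0.148). WDL5, from the ethylene-induced list, differed by 0.17 (adjusted p = 0.699), and ACO3, an ACC oxidase, by 0.13 (adjusted p = 0.877). ARR16, a type-A response regulator of the cytokinin pathway, rose by 2.60 ± 0.46. Of 7 auxin-responsive genes LBD29 fell (-1.58 ± 0.32), and of 8 expansins EXPB1 fell (-1.93 ± 0.20).

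The cell cycle genes were the only list of the 9 tested that passed in eto1-4 against Col-0. AUR1, an Aurora kinase, fell by 1.17 on the log2 scale, while AUR2 at -0.96 and MCM7 at -0.84 did not pass. The median of the 3 was -0.96, with camera's adjusted p = 0.0111 and an adjusted p = 0.564 with an estimated correlation. All 3 passed when adjusted over the list alone, against 1 over all probe sets tested.

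In total 326 probe sets were called in eto1-4 against Col-0, of which 145 were higher and 181 lower, and 157 name 1 gene. The share higher was 44.5%, against 51.3% after quantile normalization and 50.8% after median centring, so neither direction prevailed throughout. With the labelling batch as a block 942 were called. In the 8 spiked arrays, with 1 array each of Col-0 and eto1-4, all 326 kept their sign, with a median change of 1.42. On the unspiked arrays, also with 1 of each, all 326 kept it, with a median of 1.39. Choosing the probe sets from both batches together favours this. The count was 199 with only the groups compared in the fit, 191 with no filter, 72 without Col-0 replicate 1, 2 without Col-0 replicate 2, 37 without eto1-4 replicate 1, and 128 and 114 without 7303 replicate 1 and replicate 2.

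**Figure D2:**
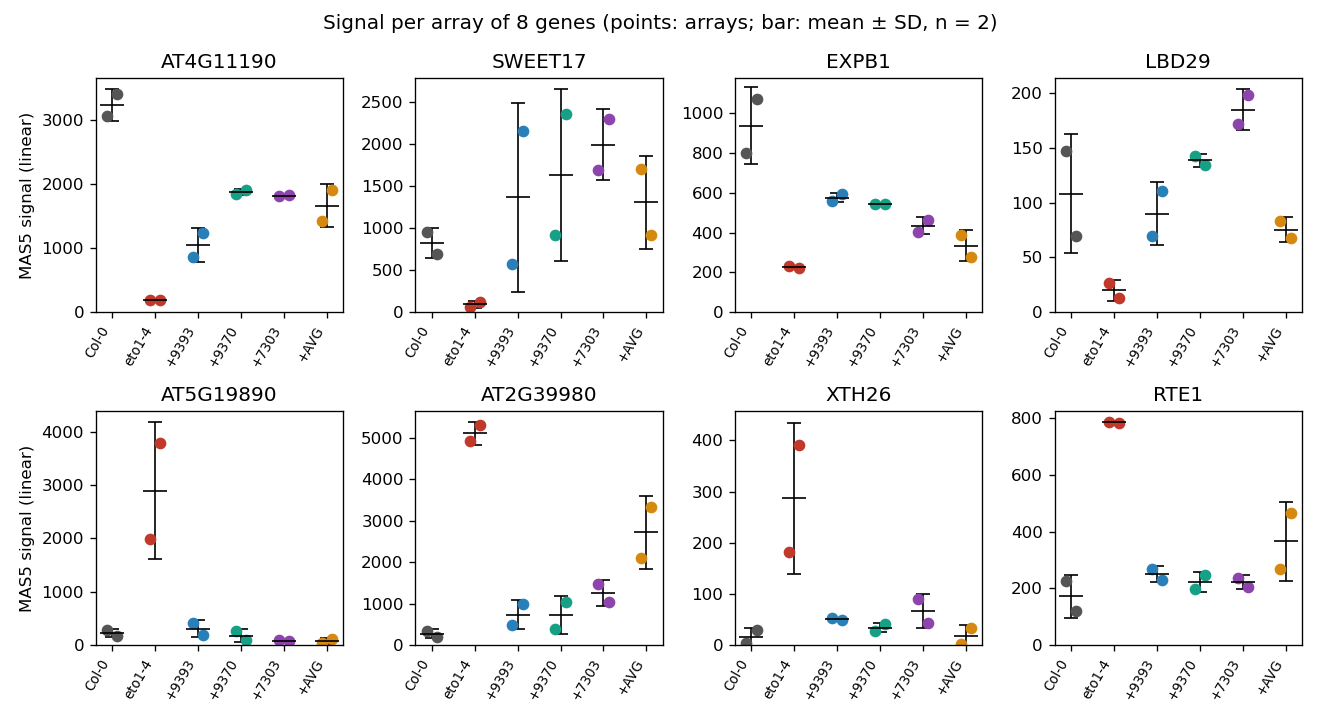
MAS5 signal on a linear axis of 8 genes in the 6 groups, with a point for each array and a bar for the mean ± SD of 2 arrays. AT4G11190 fell from 3227 in Col-0 to 187 in eto1-4 and read 1044 to 1867 under the treatments, while AT5G19890 rose from 223 to 2890 and read 79.2 to 304 under them.

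Under 9393, SWEET17, AT4G11190 and EXPB1, which fell in eto1-4, rose, and AT5G19890 and AT2G39980, which rose in it, fell. SWEET17 rose by 3.37 ± 0.61 on the log2 scale against untreated eto1-4 (adjusted p = 0.0443) and its relative SWEET16 by 1.67 ± 0.21. AT4G11190 rose by 2.33 ± 0.21 (adjusted p = 0.00321), to a signal of 1044 ± 264 (SD, n = 2), and EXPB1 by 1.26 ± 0.20. AT5G19890 reached -3.17 ± 0.54 and AT2G39980 -2.84 ± 0.47, and GH9B12, a glycosyl hydrolase of family 9, reached -2.29 ± 0.35.

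Other genes that rose most under 9393 were AT3G13980 at 2.61, AT4G10910 at 2.17, AT2G43535 at 2.12, AT2G17600 at 2.01, AT4G25250 at 1.79, the wax synthase gene WSD1 at 1.73 and AT5G44410 at 1.60. Other genes that fell most were AT5G50335 at -3.19, AT3G28310 at -2.97, AT5G18470 at -2.60, AT1G33790 at -2.22, AT4G15700 at -1.90, the pectin methylesterase family gene AT3G43270 at -1.87 and AT1G62770 at -1.73. RTE1 stood at -1.57 ± 0.30 with an adjusted p of 0.0516, and WDL5 at -0.25 (adjusted p = 0.564). With the labelling batch as a block RTE1 was called (-1.57 ± 0.29, adjusted p = 0.0226). Of the 7 auxin-responsive genes none was called, and as a list they did not pass (median 0.48, adjusted p = 0.0517). The list passed at 0.0397 without either array of Col-0, 0.0388 without 9393 replicate 1, 0.0499 without either array of 7303, 0.0282 and 0.0226 without AVG replicate 1 and replicate 2, and 0.00996 without eto1-4 replicate 2.

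For 9393 the number called was 98, with 52 higher and 46 lower. It was 578 with the labelling batch as a block and 158 in the 8 spiked arrays, 26 of them among the 98, where 16 of the 21 called genes named under the rule were not called. It was 1 with only the groups compared in the fit, 40 with no filter, 5 without Col-0 replicate 1 and likewise without Col-0 replicate 2, 0 without eto1-4 replicate 1, 161 without eto1-4 replicate 2, 3 without 9393 replicate 2, and 15 without either array of 7303.

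Under 9370, the sugar transporter genes SWEET17 and SWEET3 rose and the expansin gene EXPA9 fell. SWEET17 rose by 3.76 ± 0.61, SWEET3 by 2.60 ± 0.43 and AT4G11190 by 3.17 ± 0.21 (adjusted p = 0.000492). EXPA9 stood at -3.26 ± 0.62 (adjusted p = 0.0241), AT5G19890 at -3.92 ± 0.54, CYP718 at -2.88 ± 0.51 and XTH19 at -1.23 ± 0.20. RTE1 reached -1.73 ± 0.30 (adjusted p = 0.0209) and ARR16 -1.91 ± 0.46.

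Further genes that rose most under 9370 were AT1G72140 at 3.72, AT4G25780 at 3.14, AT3G13980 at 2.56, AT2G43535 at 2.52, AT2G17600 at 2.50, AT2G30540 at 2.25 and MSRB6, a methionine sulfoxide reductase, at 2.25. Those that fell most also included the Kunitz-type inhibitor gene AT1G72290 at -4.15, AT3G28310 at -3.24, AT5G02540 at -3.07, AT1G53080 at -3.06, AT2G39980 at -2.94, AT5G50335 at -2.79 and AT4G18650 at -2.56. EXPB1 rose by 1.18, 1 of the 8 expansins, while EXPA9 was the 1 that fell. AUR1 rose by 0.88. WDL5 stood at -0.31 (adjusted p = 0.357). Of the 7 auxin-responsive genes LBD29 rose by 1.95 ± 0.32 and IAA29 by 0.93 ± 0.22, with a list median of 0.53. Camera gave this list an adjusted p = 0.0215, and an adjusted p = 0.583 with an estimated correlation. It did not pass without eto1-4 replicate 1 (0.0909) or without 9370 replicate 2 (0.143).

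For 9370 the number called was 600, with 309 higher and 291 lower. It was 1591 with the labelling batch as a block and 580 in the spiked arrays, 210 of them among the 600, where 15 of the 27 called genes named under the rule were not called. It was 6 with only the groups compared in the fit, 374 with no filter, 284 and 292 without Col-0 replicate 1 and replicate 2, 1 without eto1-4 replicate 1, 219 and 107 without 9370 replicate 1 and replicate 2, and 254 and 261 without 7303 replicate 1 and replicate 2.

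Under 7303, SWEET17, SWEET3 and the auxin-responsive gene LBD29 rose, and the peroxidase family gene AT5G19890 fell. SWEET17 rose by 4.18 ± 0.61, SWEET3 by 2.72 ± 0.43, AT4G11190 by 3.13 ± 0.21 (adjusted p = 0.000555) and LBD29 by 2.31 ± 0.32 (adjusted p = 0.00995). AT5G19890 stood at -4.77 ± 0.54 (adjusted p = 0.00533), the calmodulin-like gene AT2G41090 at -2.99 ± 0.40, PDF2.5, a defensin-like gene, at -2.81 ± 0.52, and the plantacyanin gene ARPN at -2.74 ± 0.57. RTE1 reached -1.74 ± 0.30 (adjusted p = 0.0166).

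The remaining genes that rose most were AT1G72140 at 4.06, AT4G37220 at 3.66, AT4G22610 at 3.59, AT4G25780 at 2.95, AT1G49450 at 2.82, AT5G57670 at 2.78 and AT2G43535 at 2.60. Those that fell most also included AT1G53080 at -3.26, AT3G28310 at -3.08, AT5G57760 at -2.83, AT5G40590 at -2.83, TBL41 at -2.79 and AT4G38410 at -2.77. With the labelling batch as a block AT4G37220 (3.32 ± 0.85, adjusted p = 0.0521) and AT5G57760 (-2.55 ± 0.70, adjusted p = 0.0657) were not called. EXPB1 rose by 0.87, AUR1 rose by 0.79 and XTH19 stood at -1.06 ± 0.20, 1 of the 4 xyloglucan endotransglucosylases on the list. WDL5 stood at -0.24 (adjusted p = 0.436). The 7 auxin-responsive genes had a median of 0.93. LBD29 was the 1 member called, and camera gave the list an adjusted p = 0.0111, and an adjusted p = 0.583 with an estimated correlation.

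For 7303 the number called was 696, with 441 higher and 255 lower. It was 846 with the labelling batch as a block and 737 in the spiked arrays, 403 of them among the 696, where 6 of the 25 called genes named under the rule were not called, and the unspiked batch holds no array of 7303. It was 884 with only the groups compared in the fit, 427 with no filter, 346 without Col-0 replicate 1 and likewise without Col-0 replicate 2, 21 without eto1-4 replicate 1, and 5 and 2 without 7303 replicate 1 and replicate 2.

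Under AVG the thionin gene THI2.2 fell, and SWEET17 and the ACC oxidase gene ACO3 rose. THI2.2 stood at -2.94 ± 0.49 against untreated eto1-4 (adjusted p = 0.0148), from a signal of 205 ± 110 (SD, n = 2) to 5.55 ± 0.484. AT5G19890 stood at -4.88 ± 0.54, PDF2.5 at -3.42 ± 0.52, XTH26 at -2.99 ± 0.51 and CYP718 at -2.96 ± 0.51. SWEET17 rose by 3.53 ± 0.61, AT4G11190 by 2.99 ± 0.21 (adjusted p = 0.000871) and ACO3 by 1.16 ± 0.28 (adjusted p = 0.0423). RTE1 stood at -1.10 ± 0.30 (adjusted p = 0.0601) and WDL5 at -0.56 (adjusted p = 0.0908).

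Further genes that rose most under AVG were AT4G37220 at 3.80, AT5G57670 at 3.45, AT1G72140 at 3.27, AT2G16005 at 3.17, AT4G22610 at 3.08, AT4G04630 at 2.73, AT3G47250 at 2.66 and AT4G25250 at 2.45. Those that fell most also included AT3G28310 at -3.11, AT2G43140 at -2.99, AT5G40590 at -2.90, ARPN at -2.87 and the peroxidase family gene AT3G49960 at -2.86. Of the 4 xyloglucan endotransglucosylases on the list, which leaves out XTH26 and XTH32, XTH19 (-1.20 ± 0.20) and XTH33 (-1.60 ± 0.40) fell, and the list did not pass camera (adjusted p = 0.122). XTH33 was not called with the labelling batch as a block (-1.45 ± 0.40, adjusted p = 0.0569). ZAT10, a zinc finger gene of the oxidative stress list, stood at -1.17 ± 0.27 (adjusted p = 0.0350). The 7 auxin-responsive genes had a median of 0.52 and did not pass (adjusted p = 0.125), but passed without eto1-4 replicate 2 (0.0310) and without AVG replicate 2 (0.00972).

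For AVG the number called was 789, with 437 higher and 352 lower. It was 1104 with the labelling batch as a block and 1040 in the spiked arrays, 526 of them among the 789, where 5 of the 24 called genes named under the rule were not called, and the unspiked batch holds no array of AVG. It was 353 with only the groups compared in the fit, 537 with no filter, 487 without Col-0 replicate 1 and likewise without Col-0 replicate 2, 18 without eto1-4 replicate 1, 359 without either array of 7303, and 4 and 327 without AVG replicate 1 and replicate 2.

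The other lists did not pass in any of the 5 main comparisons. Gibberellin metabolism and response, measured by the 3 GID1 receptor genes, had adjusted p-values of 0.252, 0.848, 0.349, 0.848 and 0.671 in eto1-4 and under 9393, 9370, 7303 and AVG. In the same order xenobiotic detoxification (5 genes) had 0.663, 0.593, 0.252, 0.245 and 0.349, expansins (8 genes) 0.841, 0.986, 0.841, 0.696 and 0.841, and reference genes (3 genes) 0.841, 0.841, 0.704, 0.854 and 0.704. Xyloglucan endotransglucosylases (4 genes) had 0.210 in eto1-4, 0.148 under 9393, 0.148 under 9370 and 0.122 under 7303. Seed storage and late embryogenesis, with OLEO3, OLEO5 and PAP85, had 0.196 in eto1-4 and 0.243, 0.278, 0.252 and 0.267 under 9393, 9370, 7303 and AVG. The array of eto1-4 replicate 1, which enters all 5 comparisons, stood apart in these genes: PAP85 read 6894 there, 42.6 in replicate 2 and 5.11 to 264 elsewhere, and OLEO5 read 2041, 30.3 and 31.4 to 270. Without eto1-4 replicate 2 this list passed in all 5 comparisons, at 0.00266, 0.00298, 0.00463, 0.00553 and 0.00470, and the auxin-responsive genes passed in eto1-4 at 0.0349. Without eto1-4 replicate 1 the xyloglucan endotransglucosylases passed in all 5, at 0.0428, 0.0129, 0.0202, 0.00820 and 0.00820, and the cell cycle genes under 9393 (0.0428) and 7303 (0.0476). Without 9370 replicate 1 xenobiotic detoxification passed under 9370 (0.0479). Under the treatments cell cycle genes had 0.138, 0.148, 0.148 and 0.193, and ethylene perception and signalling had 0.349, 0.274, 0.417 and 0.854, in the order 9393, 9370, 7303 and AVG. The median of the expansins, of the GID1 genes and of the reference genes was opposite in sign to camera's direction in some of these comparisons.

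Over the 4 treatments together, eto1-4 seedlings had higher SWEET17 (3.71 ± 0.48), AT1G72140 (3.55 ± 0.63), AT4G37220 (3.201 ± 0.66), AT4G11190 (2.91 ± 0.17) and AT4G25780 (2.86 ± 0.44) than without treatment. The genes that fell most were AT5G19890 (-4.19 ± 0.43), AT1G72290 (-3.63 ± 0.79), AT3G28310 (-3.10 ± 0.41), M10 (-2.90 ± 0.72) and AT1G53080 (-2.85 ± 0.46). In total 1532 probe sets were called, 844 higher and 688 lower. The count was 2188 with the labelling batch as a block and 1431 in the spiked arrays, 837 of them among the 1532, and there M10 (-1.67 ± 0.72, adjusted p = 0.195), AT1G72290 (-2.98 ± 0.88, adjusted p = 0.0899) and AT4G25780 (2.06 ± 0.48, adjusted p = 0.0542) were not called. In eto1-4 replicate 1 and replicate 2 M10 read 1439 and 174, and AT1G72290 1196 and 255. The count was 79 without eto1-4 replicate 1, 855 and 778 without 7303 replicate 1 and replicate 2, and 858 without AVG replicate 1.

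The treatments shared many of their calls. The probe sets called under every treatment numbered 82. AT4G11190, SWEET17 and AT5G19890 were among them. Of these, 60 had also been called in eto1-4 against Col-0, with opposite sign, which sharing the untreated eto1-4 arrays favours. Simulations without a treatment effect gave 0 such probe sets in each of 20 runs. Across genes, the log2 changes correlated at 0.925 between 9393 and 9370, 0.876 between 7303 and AVG, 0.819 between 9393 and 7303, 0.812 between 9370 and 7303, 0.723 between 9370 and AVG and 0.716 between 9393 and AVG. Genes are not independent replicates. Unchanged groups sharing the same untreated arrays gave correlations of 0.495 to 0.499 in simulation, and covariances of 0.0462 to 0.0467 against observed covariances of 0.217 to 0.340. Of the calls, 97 were shared between 9393 and 9370, 444 between 7303 and AVG, and 376 between 9370 and 7303, with 0 in opposite directions. Independent lists would share 1.99, 19.0 and 14.2. Part of the excess may come from the shared controls, which are too few to divide. The simulation holds no labelling batch: 9393 and 9370 straddle the same batches, with replicate deviations correlated at 0.781, and 7303 and AVG lie wholly in the spiked batch. These are the pairs with the highest correlations.

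Of the 326 probe sets called in eto1-4, 251 lay closer to the Col-0 level than to the untreated eto1-4 level under 9393, 266 under 9370, 218 under 7303 and 191 (58.6%) under AVG. RTE1 read 172 ± 75.8 in Col-0 and 785 ± 4.42 in eto1-4, against 249 ± 28.5 under 9393, 222 ± 33.9 under 9370, 221 ± 24.5 under 7303 and 366 ± 139 under AVG (SD, n = 2). AT2G39980 read 275 in Col-0 and 5105 in eto1-4, and 733 ± 350, 721 ± 460, 1257 ± 320 and 2716 ± 874 under the treatments in that order. EXPB1 read 937 ± 193 in Col-0 and 227 ± 5.21 in eto1-4, and 575 ± 23.5, 544 ± 0.0799, 435 ± 42.6 and 334 ± 77.6 under them. PME61 fell in eto1-4 and was not called under any treatment, with changes of 1.23, 1.07, 0.90 and 0.86.

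Over the 326 probe sets, the median share of the eto1-4 shift left was 33.4% ± 3.54 (SD, n = 2) under 9393, 21.7% ± 0.819 under 9370, 28.8% ± 3.94 under 7303 and 38.2% ± 8.59 under AVG. Each SD comes from the 2 treated arrays alone. The Col-0 and untreated eto1-4 means and the 326 probe sets were held fixed, so their spread is left out. The value simulated for a treatment without effect was 89.6%, 89.5%, 89.6% and 89.3%, and 85.4%, 86.0%, 85.9% and 85.8% where the simulated eto1-4 changes were shrunk to give a similar number of calls. Probe sets called back toward Col-0 numbered 73, 178, 160 and 130, and 0 were called further away. In the spiked arrays the shares were 53.1%, 42.5%, 49.7% and 61.6%, over the 202 probe sets called there. They were 55.6%, 46.2%, 51.2% and 64.5% without Col-0 replicate 1, 18.6%, 9.42%, 3.63% and 13.3% without Col-0 replicate 2, and 17.2%, 17.0%, 16.1% and 23.3% without eto1-4 replicate 2, with AVG at 23.61% without AVG replicate 2.

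**Figure D3:**
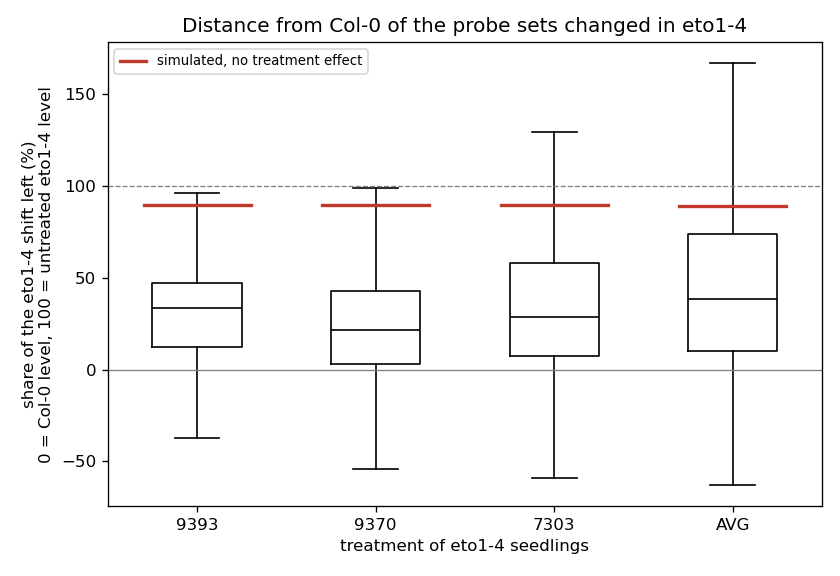
Share of the eto1-4 shift left (%) for the 326 probe sets called in eto1-4, by treatment, where 0 is the Col-0 level and 100 the untreated eto1-4 level. Boxes give the median and quartiles, whiskers reach 1.5 box lengths, points beyond are not drawn, and red lines give the simulated share without a treatment effect. Medians lie at 21.7% to 38.2%, below the simulated 89.3% to 89.6% of the unshrunk simulation.

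Seedlings of eto1-4 with AVG differed from Col-0 in many genes. THI2.2 stood at -4.35 ± 0.49 (adjusted p = 0.00954), XTH32 at -3.08 ± 0.68, AT5G04120 at -3.91 ± 0.87, AT4G22490 at -3.13 ± 0.86 and AT3G56290 at -3.09 ± 0.70. Under AVG both THI2.2 (5.21 and 5.90) and AT5G04120 (6.20 and 21.6) read below the offset, which sets the size of their change, and AT5G04120 read 167 and 1487 on the Col-0 arrays. AT3G05950 rose by 3.89 ± 0.81, AT4G37220 by 3.38 ± 0.84, AT4G04630 by 3.23 ± 0.51, AT2G39980 by 3.21 ± 0.47 and AT4G25580 by 3.07 ± 0.31. Outside the rule, and chosen after their values were seen, are the 6 list members called here. They were the methionine gamma-lyase gene MGL at 2.67 (adjusted p = 0.0362), ACO3 at 1.29 (0.0254), EXPB1 at -1.43 (0.0135), PORB, a protochlorophyllide reductase, at -1.48 (0.0299), UGT78D2 at -1.87 (0.0466) and XTH19 at -0.76 (0.0451).

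Against Col-0, 1365 probe sets were called for AVG, 653 higher and 712 lower, so that 47.8% were higher, against 57.9% after quantile normalization and 60.5% after median centring. For 9393, 9370 and 7303 limma called 0, with 1439, 1815 and 3493 probe sets at an unadjusted p under 0.05, against 4131 for AVG. The count for AVG was 1951 with the labelling batch as a block and 2619 in the spiked arrays, and for 9393, 9370 and 7303 it was 4, 0 and 286 with the block and 386, 558 and 1692 in the spiked arrays. For AVG it was 161 and 0 without Col-0 replicate 1 and replicate 2, 883 and 878 without 7303 replicate 1 and replicate 2, and 0 and 2 without AVG replicate 1 and replicate 2; for 7303 it was 580 and 575 without 9393 replicate 1 and replicate 2, 364 and 351 without 9370 replicate 1 and replicate 2, 177 and 178 without eto1-4 replicate 1 and replicate 2, and 8 without Col-0 replicate 1, where 9393 had 2 and 9370 had 4.

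Between the treatments, all at 10 µM, THI2.2 was the only gene called. It was 4.56 ± 0.49 higher under 9393 than under AVG (adjusted p = 0.0394) and 4.64 ± 0.49 higher under 9370 than under AVG (adjusted p = 0.0337). Under AVG its signal lay below the offset of 22.4, so the size of these differences depends on the offset (6.84 and 6.92 without one). Its signal was 637 ± 27.8 under 9393, 693 ± 231 under 9370, 253 ± 199 under 7303, 5.55 ± 0.484 under AVG and 550 ± 101 in Col-0 (SD, n = 2). Limma called 0 probe sets between 9393 and 9370, 9393 and 7303, 9370 and 7303, and 7303 and AVG. The probe sets at an unadjusted p under 0.05 numbered 132, 761, 960 and 587 there, and 1745 and 1907 between AVG and 9393 and 9370. The 132 and the 587 are fewer than evenly spread p-values over 14830 probe sets would give. The shared error may thus be too large for 7303 and AVG, whose SD between replicates was 0.215 and 0.269. It was 0.413 and 0.424 under 9393 and 9370, so spread from those other groups does not account for the 132. Replicate deviations of 9393 and 9370, correlated at 0.781, count toward the error but partly cancel in their difference. The lack of calls does not show that the treatments act alike. The median 95% interval of a difference reached 0.56 on the log2 scale to either side for a single probe set, before adjustment over 14830. The power of the comparisons between compounds was not simulated. THI2.2 was not called between treatments with the labelling batch as a block (4.64 ± 0.52 for 9393, adjusted p = 0.0894, and 4.72 ± 0.52 for 9370, adjusted p = 0.0773) or in the spiked arrays (4.52 ± 0.61, adjusted p = 0.289, and 4.30 ± 0.61, adjusted p = 0.179), where the differences were of similar size and fewer residual degrees of freedom were left. Both calls were lost without either array of Col-0, 9393, 9370 or AVG, where the counts were 0, and 3 were called between 9370 and AVG without either array of 7303, and 1 between 7303 and AVG without AVG replicate 2.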

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

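All tests of explanations in this part were chosen after the results were seen.

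THI2.2 differed between treatments by the test of the difference itself, by 4.56 on the log2 scale between 9393 and AVG and by 4.64 between 9370 and AVG. The 25S ribosomal RNA probe set and the poly-A spike control dap 3' enter no comparison. The 25S signal ran from 494 to 12724 on arrays of eto1-4 seedlings, above both Col-0 arrays. The spike read from 149 upward on 8 arrays. These were both arrays of 7303 and of AVG, and replicate 2 of Col-0, untreated eto1-4, 9393 and 9370. The spike thus divides labelling batches, and comparisons of 7303 or AVG with the other groups partly follow that division.

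The 25S signal was higher on every eto1-4 array than on Col-0. The labelling batch is a technical candidate, since ribosomal RNA could be primed differently in each. Within the unspiked batch the lowest eto1-4 array was 47.0 times Col-0, and within the spiked batch 1.86 times. This order within batches follows once every eto1-4 array exceeds both Col-0 arrays. A batch acting alike on all its arrays leaves no gap inside a batch. However, each batch holds a single Col-0 array, and the arrays of 7303, both spiked, differed 11.7-fold. The ratios therefore cannot decide whether the labelling batch is the cause. A batch effect particular to eto1-4 seedlings cannot be told apart either. The genotype and a difference in RNA preparation also remain open, both untested.

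Replicate 1 of 9393 and of 9370 deviated together from their replicate 2, with a correlation of 0.781 across genes. If the unspiked batch shifted all its arrays alike, the Col-0 arrays should deviate by the same amount, but their slope on this shared deviation was 0.0419 ± 0.00662 (SD over 200 resamplings of probe sets). If carried-over ribosomal RNA were the cause, 7303, whose 25S signal differed 11.7-fold between replicates, should follow, but its slope was -0.0175. Untreated eto1-4 had a slope of 0.377 ± 0.0119. Each slope rests on 1 pair of arrays, and its SD leaves out the spread between arrays. Deviations of eto1-4 correlated at 0.383 with 9393 and 0.311 with 9370. Those of AVG, whose arrays share a batch, reached -0.272 with 7303 and -0.236 with eto1-4. Whether untreated seedlings share the deviation of 9393 and 9370 thus cannot be decided. A batch effect particular to eto1-4 seedlings, and a difference between sets of plants, may each account for that deviation and remain open, since no array separates them.

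AVG differed from Col-0 in 1365 probe sets while 9393, 9370 and 7303 differed in 0. For 7303 a candidate explanation is that spread between arrays of other groups enters the shared error. With only the 4 arrays of 7303 and Col-0 in the fit, 3117 probe sets were called, against 3260 for AVG in its own fit, as that explanation predicts. These fits also rest on 2 residual degrees of freedom. Both arrays of 7303 and of AVG are spiked while Col-0 straddles the batches, so the labelling batch may add to these calls. For 9393 and 9370 the labelling batch cannot be told apart from the absence of a difference: the spiked arrays gave 386 and 558 calls, but their error rests on 2 residual degrees of freedom from 7303 and AVG alone, and fits of the compound and Col-0 arrays gave 0. Whether AVG acts beyond ethylene in these seedlings was not tested.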

How the results depend on the processing

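The fits with the labelling batch as a block and with the spiked arrays alone, and gene lists with an array left out, were chosen after the data were seen. The cause of each difference was not tested. Leaving out arrays or groups also removes residual degrees of freedom. Either array of eto1-4 removes as many, yet the results without replicate 1 and without replicate 2 differed. That loss alone therefore does not account for the results without eto1-4 replicate 1. None of the named genes reversed under any alternative run. In the 5 main comparisons, genes that rose or fell most had to change the same way in both pairs of equal replicate number. They also had to be called, so the selection favours this lack of reversals. Where both groups compared straddle the labelling batches, the spiked arrays hold only the replicate 2 pair, so these genes could not reverse there. With no filter 115 of 151 gene results kept their side of the threshold, with quantile normalization 144, with median centring 143, with the labelling batch as a block 145, in the spiked arrays 90 and with only the groups compared 87. Without eto1-4 replicate 1 the number was 33, the fewest. Dim signals limit the filter and offset choices, since no detection calls were used.

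The replicate number does not pair the samples in all groups: same-numbered arrays deviated with correlations of -0.272 to 0.781 across the 15 pairs of groups. In Col-0, eto1-4, 9393 and 9370 the number follows the labelling batch. There the correlations were 0.781 (9393 and 9370), 0.383 (9393 and eto1-4) and 0.311 (9370 and eto1-4). With Col-0 they were 0.176 (eto1-4), 0.106 (9393) and 0.0262 (9370). With the replicate block the count for 9393 was 164, that for 7303 against Col-0 354, and the share left under 9370 20.7%; the block changed no gene list call.

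Without an offset 1 probe set was called between 7303 and AVG, and the share under 9370 was 20.4%. With double the offset 0 were called between AVG and 9393 or 9370. With no filter the counts were 191 in eto1-4, 40 for 9393, 374 for 9370, 427 for 7303, 854 for AVG against Col-0 and 0 for AVG against 9393 and 9370, and the share under 9370 was 19.6%. With the 60th percentile filter they were 210 in eto1-4 and 2 for 7303 against Col-0, and that share was 19.8%. Quantile normalization gave 0 between 9393 and AVG. Median centring gave 225 for 7303 against Col-0. Without the trend 0 were called between 9393 and AVG, and the share under 9370 was 22.9%. With only the groups compared the counts were 199 in eto1-4, 1 for 9393, 6 for 9370, 353 for AVG, 3117 for 7303 against Col-0 and 3260 for AVG against Col-0, and the shares were 26.4%, 18.0% and 22.5% under 9393, 9370 and 7303. With a log2 change of at least 1 the counts were 661 over the 4 treatments and 854 for AVG against Col-0, and the share under 9370 was 22.8%.

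With the labelling batch as a block the counts were 942 in eto1-4, 578 for 9393, 1591 for 9370, 4 and 286 for 9393 and 7303 against Col-0, and 0 for AVG against 9393 and 9370; the shares under 9370 and AVG were 20.7% and 47.3%. In the spiked arrays they were 202, 158, then 386, 558, 1692 and 2619 against Col-0, and 0 for AVG against 9393 and 9370; the shares were 53.1%, 42.5%, 49.7% and 61.6%, and 7 list calls were made, against 3 in the main fit of all arrays. Camera with an estimated correlation made 0 list calls and fry 10.

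Leaving out each array in turn gave 2 to 416 in eto1-4, 0 to 161 for 9393, 1 to 682 for 9370, 2 to 1010 for 7303, 4 to 1123 for AVG and 79 to 2074 over the 4 treatments. Against Col-0 it gave 0 to 2, 0 to 4, 0 to 580 and 0 to 1691 for 9393, 9370, 7303 and AVG. Between treatments it gave 0 to 1 for 9393 and AVG, 0 to 3 for 9370 and AVG, 0 to 1 for 7303 and AVG, and 0 for the other pairs. Shares ran from 17.2% to 55.6%, 9.42% to 46.2%, 3.63% to 51.2% and 13.3% to 64.5%, list calls from 2 to 11, and the mean correlation between treatments from 0.670 to 0.882.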

Other observations

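The tests in this part were chosen after the data were seen. Gene families sharing the letters of their symbol, with at least 8 measured members, were tested with camera in the 5 main comparisons, 21 families and 105 tests in all. The serine carboxypeptidase-like genes (SCPL) were lower in eto1-4 than in Col-0, with 12 of 14 members negative, a median of -0.59 and an adjusted p of 0.0313, or 0.815 with an estimated correlation. SCPL45, at -1.24 (adjusted p = 0.0283), was the 1 member called. The autophagy genes (ATG) did not pass, although 8 of 8 were positive with a median of 0.34 (adjusted p = 0.0675). ATG8E was the highest at 0.73 and ATG8F stood at 0.53.

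Of the genes called in eto1-4 against Col-0 but outside the rule for named genes, 5 are given here, picked after their values were seen. UPB1, a transcription factor acting on peroxidase genes in roots, rose by 2.55 (adjusted p = 0.00666), ARL, a relative of the organ growth gene ARGOS, by 2.51 (0.0153), EEL, a bZIP transcription factor, by 2.40 (0.0188) and IAGLU, an auxin glucosyltransferase, by 2.099 (0.00958). SWEET16 stood at -1.28 (0.0217).

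The first principal component of the tested probe sets took 39.97% of the variance. Replicate 1 of 9393 and of 9370 scored -30.4 and -22.2 on it, on the side of Col-0 (-26.4 and -27.5) and untreated eto1-4 (-51.1 and -17.9). Their replicate 2 scored 25.4 and 27.1, on the side of 7303 and AVG (25.7 to 36.2).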
